A study of Homo sapiens with 2 samples.

How the data were processed

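Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate DNA bound by the transcription factor GATA6 in PaTu8988S, an established human pancreatic ductal adenocarcinoma (PDAC) cell line. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated and incubated with an anti-GATA6 antibody, short DNA fragments were selected on a gel, and adapter-ligated libraries were amplified and sequenced on an Illumina Genome Analyzer IIx. The series has 2 samples with a group, 1 GATA6 ChIP library and 1 input library. Per the labels' protocols, the input was a blend of the inputs of 3 samples. The ChIP library was analysed as its peak list, and no values of the input library were used here.

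Per the submitters' processing notes, CASAVA 1.8 and BWA 0.5.9-r16 were used, and the genome build was hg19 (GRCh37). The peak caller, its settings, the scaling of the libraries and the treatment of reads with several possible positions are not given in the sources used here. Whether the peaks were called on 1 immunoprecipitation or on pooled ones is not stated beyond the single ChIP sample in the labels. The deposited peak list names 9 columns in its first line, while each line after it holds 6 values, so the names cannot be matched by position. The values were read as chromosome, start, end, strand, fold enrichment and false discovery rate (FDR). The fifth value was taken as the authors' fold enrichment, a linear ratio of ChIP signal over background deposited for each peak, because it is no genome position and falls as the sixth value rises. The sixth value was taken as the authors' FDR in percent, as deposited, because the lines are sorted by it and it stays below 1. Fold and FDR are each peak's own values from the authors' peak caller and were used only to describe, rank or filter peaks within this list. No summit, read count or p-value of a peak was used here, so the depth is unknown and no fold carries an error. Coordinates are printed as deposited, and width was taken as end minus start.

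All values were computed in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. The design fixed before the data were examined included the share of summits in promoters, distances to transcription start sites, GATA and partner motifs, and gene lists for epithelial, mesenchymal, classical and basal-like PDAC, pancreatic, WNT, receptor kinase, erythroid, cardiac, lymphocyte, neuronal and ribosomal genes. These parts needed the sequence and gene annotation of hg19, which were not used here. The gene table at hand described another build, GRCh38, and positions were not converted. No list or motif was therefore tested and no peak was assigned to a gene. Following the rule set for that case, the 10 best-ranked peaks and the 5 clusters with the most peaks are given by position. Ranking used FDR with ties broken by fold in place of the missing p-value, and peak midpoints replaced summits.

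Location was analysed for chromosomes 1 to 22 and X. Peaks per Mb were computed over the span from the first to the last peak of each chromosome. Their 95% intervals came from 2000 bootstrap resamples of 5 Mb blocks. The measure was added after the data were examined, since only counts had been planned without chromosome lengths, and the planned exact binomial test per chromosome was not run for the same reason. The relations across chromosomes and the comparison of near with isolated peaks were also added after the data were examined. Clustering was measured as the share of neighbouring midpoints closer than the cluster distance, 12.5 kb, against 1000 sets of random positions with the same number per chromosome inside its span (one-sided permutation). Shares of peaks have 95% Wilson intervals and medians have 95% order-statistic intervals. These intervals cover counting error over peaks in 1 library. Peaks are not independent replicates, and with 1 library per group no test between conditions exists. Relations across the 23 chromosomes used Spearman and Pearson coefficients with permutation p-values and Benjamini-Hochberg adjustment over 3 relations.

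The procedures were tested on simulated data. For 26244 uniformly placed peaks in 20 runs, the mean ratio of observed to random close neighbours was 1.00, and 0 runs gave p under 0.05. When some of these peaks were placed beside another peak, 20 of 20 runs gave p under 0.05, with a mean ratio of 2.33. The block bootstrap covered the true density in 94% of 200 simulated chromosomes of about 800 uniformly placed peaks. Its coverage for clustered peaks, or for chromosomes of few blocks such as chromosome 22 with 7, was not simulated. Alternatives were the 13137 peaks with the best FDR, a fold of at least 10, cluster distances of 5 and 50 kb, and counting peaks closer than 12.5 kb as 1. Random positions kept inside the same 1 Mb or 100 kb window as each peak, and random peaks that kept the real widths without overlap, were alternatives added after the data were examined.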

Results

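GATA6, a zinc-finger transcription factor of the endoderm that acts in pancreas development, was mapped on chromatin of PaTu8988S cells to locate its binding sites across the genome. The study has 1 GATA6 ChIP library and 1 input library, so no value below has a replicate error. The authors' list held 26274 peaks at an FDR of at most 0.99%. Together the peaks covered 25.3 Mb. Of these peaks, 26244 lay on chromosomes 1 to 22 and X. The number of reads behind each peak is unknown.

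The listed GATA6 peaks were mostly narrow, and their folds lay well above background, which selection by FDR itself favours. The median fold enrichment was 20.83 (95% interval 20.79 to 20.83), with quartiles of 14.58 and 31.59 and a range of 4.88 to 589.02. The median width was 833 bp (95% interval 826 to 839), with quartiles of 580 and 1210 bp and a range of 190 to 8140 bp. A fold of 100 or more was listed for 824 peaks, and 208 peaks were 3 kb wide or more. The authors' FDR was 0 for 4402 peaks, or 16.8% of the list (95% Wilson interval 16.3 to 17.2%). These 4402 peaks had a median fold of 53.12 and a median width of 1274 bp, against 18.75 and 771 bp for the 21872 peaks with an FDR above 0. The 95% intervals of the medians did not overlap between these classes, but the FDR that defines them itself goes with both fold and width.

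**Figure D1:**
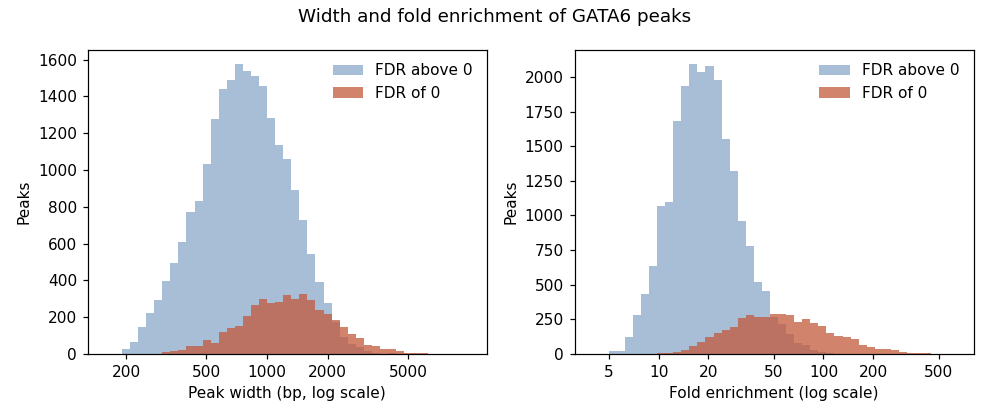
Histograms of peak width in bp (left, log scale) and fold enrichment (right, log scale) for all 26274 GATA6 peaks of 1 library, with the number of peaks on the vertical axes. The 4402 peaks with an FDR of 0 (red) have a median width of 1274 bp and a median fold of 53.12, and the 21872 peaks with an FDR above 0 (blue) have medians of 771 bp and 18.75.

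Within the list, the rank of a GATA6 peak by fold said little about its rank by width. Across all 26274 peaks, fold and width were nearly unrelated in rank (Spearman rho of -0.02, across peaks, which are not independent replicates). Each went with a lower FDR, with a rho of -0.63 for fold and -0.54 for width. The fall of fold with FDR also served to identify the fold values, so it is no separate finding. An FDR of 0 was reached by 2.65% of peaks in the narrowest of 10 width classes of similar size (190 to 414 bp; 95% Wilson interval 2.10 to 3.34%) and by 49.6% in the widest class (1651 to 8140 bp; 47.7 to 51.5%). The median fold fell from 21.88 in the narrowest class to 19.53 in the eighth and was 22.61 in the widest, so the coefficient near 0 averages both directions. The list also ends at an FDR of 0.99%, so peaks both narrow and low in fold may be missing. The coefficient therefore describes listed peaks only.

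The 10 best-ranked GATA6 peaks were spread over 7 chromosomes, and each had an FDR of 0. Positions are on hg19, and the genes and features at these sites were not analysed here. The highest fold, 589.02, was listed for a peak of 1610 bp on chromosome 1 from 3166470 to 3168080. It was followed by a fold of 550.00 on chromosome 17 from 79366264 to 79368130, and by 503.12 on chromosome 1 from 42630091 to 42630897. On chromosome 7, a peak from 412596 to 413843 had a fold of 465.62, and one near the other end of the chromosome, from 157667320 to 157668479, had 397.73. On chromosome 6, a peak from 153323525 to 153324380 had a fold of 443.75, and one from 34530030 to 34531747 had 397.29. The remaining 3 were a peak on chromosome 16 from 88574355 to 88576520 with a fold of 436.01, a peak on chromosome 3 from 98311691 to 98313189 with 402.78, and a peak on chromosome 19 from 961953 to 962850 with 401.37. The folds of 550.00, 503.12, 465.62 and 443.75 were whole multiples of 3.125 (tolerance 0.0055), and the others were not. A fold is a ratio over background, so ranks by fold do not by themselves single out the strongest binding. The widest peaks, singled out after their values were seen, were 8140 bp on chromosome 7 from 5462457 to 5470597 (fold 84.90) and 7916 bp on chromosome 18 from 20675173 to 20683089 (fold 22.96). Of the 100 peaks of highest fold, 28 lay within 5 Mb of an end of a chromosome, against 14.5 ± 3.44 (mean ± SD) in permutations of fold within chromosomes. This comparison was chosen after the data were examined, and its ratio ran from 1.21 to 4.11 with other limits.

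GATA6 peaks were densest on chromosome 19, known as a gene-dense chromosome, and sparsest on chromosome X. Chromosome 19 held 1522 peaks, or 25.9 per Mb of its span (95% bootstrap interval over 5 Mb blocks 17.8 to 33.6). Chromosome 17 followed with 17.9 per Mb (12.9 to 22.6), chromosome 22 with 16.7 (12.4 to 21.9) and chromosome 20 with 14.1 (10.4 to 18.6). Chromosome X held 492 peaks, or 3.24 per Mb (2.38 to 4.17). Chromosome 4 had 4.87 per Mb (3.76 to 6.21) and chromosome 18, a gene-poor chromosome that carries the GATA6 gene itself, had 5.80 (4.07 to 7.59). Chromosome 1 held the largest number, 2456 peaks, at 9.89 per Mb (7.95 to 11.9). The intervals of chromosomes 17, 19, 20 and 22 did not overlap those of chromosomes 4, 18 and X. Gene density and DNA copy number were not measured here, and the spans include the long stretches without peaks given below.

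**Figure D2:**
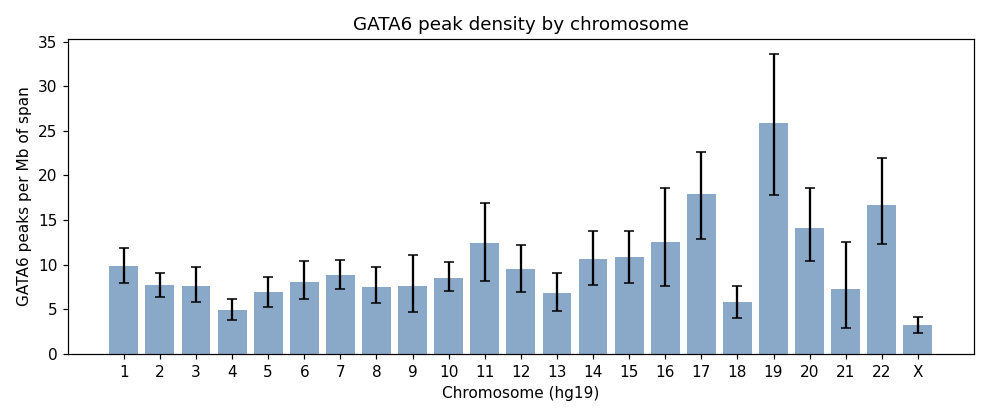
GATA6 peaks per Mb between the first and last peak of each chromosome (bars), with 95% intervals from a bootstrap over 5 Mb blocks (lines), for 26244 peaks of 1 library. Chromosome 19 has the highest density, 25.9 per Mb, and chromosome X the lowest, 3.24 per Mb.

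Fold enrichment varied less between chromosomes than peak density. The median fold ranged from 18.01 on chromosome 20 (95% interval 17.24 to 18.75) to 23.96 on chromosome 4 (23.22 to 25). On chromosome X it was 23.22 (21.87 to 24.46) and on chromosome 21 it was 23.44 (22.87 to 26.54). Whole multiples of 3.317 (tolerance 0.0055) made up 8.18% of the folds on chromosome 4, 8.74% on X, 11.9% on 21, 8.90% on 22 and 10.9% on 18, where the median fold was 21.05. They made up 1.02% on chromosome 20 and 1.44% on chromosome 11, where the median fold was 19.37. An FDR of 0 was reached by 9.96% of the chromosome X peaks (49 of 492; Wilson interval 7.62 to 12.9%) and by 11.8% on chromosome 9 (10.0 to 13.9%), against 19.5% on chromosome 2 (17.7 to 21.3%). Over the 23 chromosomes, density rose with the median width (Spearman rho of 0.67, permutation p = 0.00072, adjusted p = 0.0022; Pearson r of 0.62, permutation p = 0.0011, adjusted p = 0.0032). Without chromosomes 17 and 19, whose densities lie farthest from the median, r was 0.51. Density fell with the median fold by rank (rho of -0.55, permutation p = 0.0084, adjusted p = 0.013) but not past the threshold by Pearson's r (-0.40, permutation p = 0.063, adjusted p = 0.095; -0.45 without the same chromosomes). Density and the share of peaks with an FDR of 0 showed no relation that passed the test (rho of -0.03, permutation p = 0.88, adjusted p = 0.88; r of -0.03, permutation p = 0.89, adjusted p = 0.89; r of 0.08 without the same chromosomes).

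GATA6 peaks lay in clusters. Of 26221 neighbouring pairs, 32.0% had midpoints within the cluster distance set before the data were examined, against 12.2% ± 0.188 (mean ± SD of 1000 random sets) for random positions on the same chromosomes. This is a ratio of 2.63 (one-sided permutation p = 0.001, the smallest that 1000 sets can give). When random positions stayed within the same 1 Mb window as each peak, 21.02% of pairs were as close, and the ratio was 1.52. Within the same 100 kb window the random share was 27.2% and the ratio was 1.18. In both cases the observed share exceeded all 1000 random sets (one-sided permutation p = 0.001).

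Joining midpoints within the cluster distance gave 4824 clusters of 2 or more peaks, which held 13226 peaks, or 50.4% of those placed. There were 418 clusters of 5 or more peaks and 28 of 10 or more. The largest cluster, on chromosome 16 from 88509095 to 88597784, held 20 peaks over 88.7 kb, including the sixth-ranked peak of the whole list, and 7 of its peaks had an FDR of 0. A cluster on chromosome 22 from 46423161 to 46484445 held 16 peaks, with a highest fold of 110.42. The next 3 clusters held 14 peaks each. They lay on chromosome 19 from 908635 to 991576 (highest fold 401.37), on chromosome 9 from 140082762 to 140150104 (149.22) and on chromosome 19 from 1240027 to 1292228 (122.40). The densest 1 Mb window of the genome was on chromosome 19 between 1 and 2 Mb, with 83 peaks against a mean of 8.95 per Mb of span. Windows on chromosome 11 between 65 and 66 Mb, with 66 peaks, and on chromosome 19 between 49 and 50 Mb, with 65 peaks, came next. These windows were also singled out after the values were seen.

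**Figure D3:**
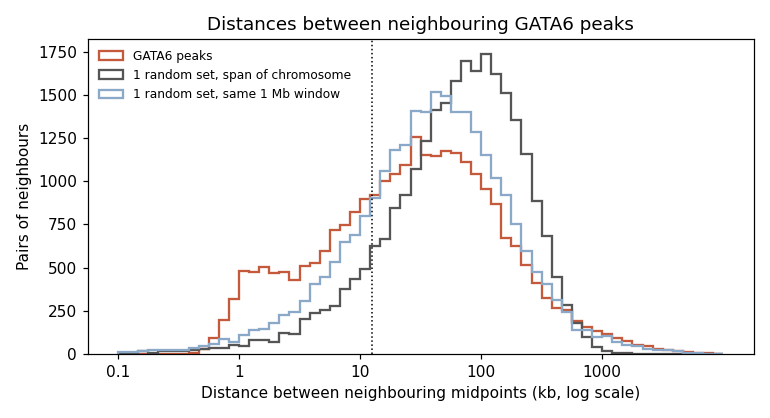
Distances in kb between the midpoints of neighbouring peaks (log scale) against the number of pairs, for the GATA6 peaks (red), 1 random set over the span of each chromosome (grey) and 1 random set within the same 1 Mb windows (blue). The dotted line marks the cluster distance, below which 32.0% of GATA6 pairs lie.

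Peaks with a near neighbour reached an FDR of 0 more often than isolated peaks. The share was 18.6% among the 13226 peaks with a neighbour within the cluster distance and 14.9% among the other 13018, a difference of 3.71 percentage points (95% interval 2.71 to 4.60, bootstrap over 5 Mb blocks). With both classes weighted to the same widths, the difference was 2.48 points (1.571 to 3.314). The share was 22.5% for peaks whose nearest neighbour lay 2.5 to 5 kb away. It was 7.09% (5.81 to 8.64%) for those with a neighbour within 1 kb, whose median width was 650 bp. It was 5.29% (3.05 to 9.01%) for the 227 peaks with no other peak within 500 kb, whose median width was 527 bp. Fold did not rise with nearness. The median fold was 19.88 with a neighbour within 1 kb and 19.79 at 1 to 2.5 kb. It was 22.79 at 100 to 500 kb and 23.22 with no other peak within 500 kb.

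Some long stretches held no GATA6 peak. The longest ran for 24.2 Mb on chromosome 9 from 42251562 to 66457812, for 21.3 Mb on chromosome 1 from 121337265 to 142618382 and for 13.0 Mb on chromosome 16 from 33619490 to 46616948. Each of these crosses the centromere and the large heterochromatic block known on that chromosome. A stretch without peaks on chromosome 6 from 28368037 to 33538573, 5.17 Mb long, lies on a chromosome arm and spans the major histocompatibility complex, the gene-dense region of the antigen-presentation genes. The equally long flanks of this stretch held 131 and 120 peaks. Only the gaps on chromosomes 1 and 16 had a poorer flank with more peaks. On chromosome 17, no peak lay between 43374289 and 44849096, and the flanks of that gap held 42 peaks each. hg19 has alternative haplotype sequences for both the chromosome 6 and the chromosome 17 region. The list held 2 peaks on such a sequence of chromosome 6 and 1 on that of chromosome 17. The gaps on chromosomes 6 and 17 were singled out after the values were seen.

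**Figure D4:**
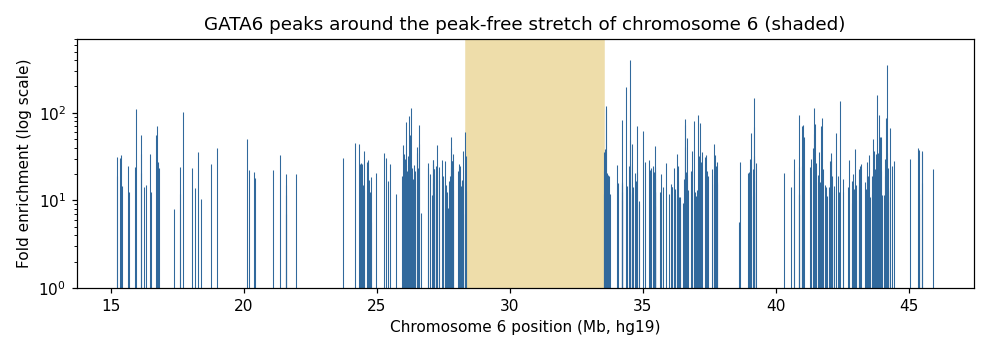
Fold enrichment (log scale) of each GATA6 peak (vertical line) along part of chromosome 6 in Mb of hg19, with the stretch from 28368037 to 33538573 shaded. The shaded stretch holds no peak, and its flanks of equal length hold 131 and 120.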

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

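Both results below lie outside chromosomes 1 to 22 and X, and were picked out because their counts exceed the 3 that a count of 0 allows. The list held 26 peaks on 10 contigs and alternative haplotype sequences, with a median fold of 19.23 (range 8.33 to 121.09) and a median width of 989 bp. Of these, 11 had an FDR of 0, or 42.3% (95% Wilson interval 25.5 to 61.1%), against 16.7% (16.3 to 17.2%) of the placed peaks. Most of these 11 lay on a few contigs that held several peaks each. The peaks are therefore not independent, and the interval covers counting error only. Repeated sequence on these contigs was not examined. The list also held 4 peaks on chromosome Y, with folds of 26.54 to 76.29, widths of 305 to 689 bp and FDR values of 0.02 to 0.84%. Whether the cells carry a chromosome Y was not examined here. Reads from similar sequences elsewhere were not excluded, so these peaks do not show binding on chromosome Y.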

How the results depend on the processing

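Of 36 values under alternative settings, 26 were counted as unchanged and 10 as moved. Medians and shares were unchanged if inside the 95% interval of the full list, and the peak count if within a set factor. For ratios, unchanged covers the direction of the excess and not its size. The clustering ratio of 2.63 in the main setting fell to 1.18 in 1 alternative and was still counted as unchanged. The 26 include the overlapping limits used for the highest folds near chromosome ends, which are not separate results. The 13137 peaks with the best FDR had a median width of 1084 bp, a median fold of 29.46, and an FDR of 0 in 33.508% of peaks. They gave 12.343 peaks per Mb on chromosome 19 and 1.388 on chromosome X. These shifts follow from the construction, which keeps fewer and better peaks. Keeping only folds of at least 10 gave a median width of 817 bp, a median fold of 21.85 and an FDR of 0 in 17.871% of peaks, outside the narrow counting intervals of the full list. This follows from leaving out the weakest peaks. Counting peaks within the cluster distance as 1, which removes peaks by construction, lowered chromosome 19 to 14.514 per Mb. The ratio of chromosome 19 over X stayed between 5.42 and 8.89 in these alternatives. The excess of close neighbours over random positions ranged from a ratio of 1.18, with random positions kept in the same 100 kb windows, to 3.52, for neighbours closer than 5 kb, each with a one-sided permutation p = 0.001. The excess of the highest folds near chromosome ends ranged from a ratio of 1.21 to 4.11 over 12 pairs of limits (one-sided permutation p of 0.0001 to 0.0124), and from 1.27 to 4.83 with the highest peak of each cluster alone (p of 0.0001 to 0.0316). These settings near ends, and those that drew random positions in windows or without overlap, were chosen after the data were examined. The alternatives for promoters, start sites, motifs and gene lists were not run, for want of hg19 sequence and annotation. With 1 library no replicate could be left out, and without read counts the list cannot show which weak sites fell below its threshold.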

Other observations

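The tests of width, of weak peaks and of chromosome ends in windows of low step share were set before their results were seen; the tests of a chance step and of chance placement, and all 3 tests on chromosome 6, were chosen afterwards.

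The stretch of chromosome 6 across the major histocompatibility complex held no GATA6 peak, although its flanks held 131 and 120. Of 474 gaps of 1 Mb or more, 3, or 0.633%, had flanks as rich: this gap and those across the centromeres of chromosomes 1 and 16. This share met the outcome set against ordinary variation of peak density. Ordinary variation nevertheless stays open, because the gap was singled out for its length and flanks, and shorter gaps have shorter flanks. A candidate explanation is that reads shared with alternative haplotype sequences of hg19 had no single position and were not used: the gap in the matching region of chromosome 17 ranked 14 of 26221 by its flanks, in the first 0.0534%. That test is lenient, since the rank favours long gaps and this gap was picked as the longest in its part of chromosome 17. The rank was taken among all gaps, whose median length was 28.4 kb, and not among the 474 of 1 Mb or more. It therefore adds little weight to the candidate explanation. A gap on chromosome 10 from 106113939 to 111612074, with flanks of 126 and 82 peaks, ranked above the chromosome 17 gap. The 2 peaks on an alternative haplotype sequence of chromosome 6 (folds of 39.80 and 24.24) met the outcome first set against a complete loss of this DNA, but that reading was withdrawn after the result was seen, because 2 narrow peaks of 225 and 430 bp are few and reads from similar sequences elsewhere were not excluded; a partial loss or a real lack of binding was not tested.

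The fold values were not continuous: of 24047 values up to 60, 16.7% were whole multiples of 3.125 and 4.18% of 3.317 (tolerance 0.0055), and peaks on the 3.317 step gathered in regions such as chromosome 9 between 0 and 10 Mb (16 of 30 peaks) and chromosome 18 between 70 and 80 Mb (14 of 30). Chance multiples are argued against by a step picked on some chromosomes and tested on others, without the values on 3.125: among 3001 steps the even-numbered chromosomes gave 3.317, which held 4.944% of 11144 values on the odd-numbered ones and X (99th percentile of other steps 2.597%, highest 5.44% for 2.604), while picking on the latter gave 2.604 itself, with 4.85% of 8887 values on the even-numbered ones (2.64%). Narrow peaks are argued against as the whole cause, since the spread over 262 windows given their widths was 843.3, against at most 315.9 in 1000 permutations. Low local background is consistent with the median fold of weak peaks off the step, which rose with the share on it (Spearman rho of 0.449 over 258 windows, above all 257 other circular shifts, the highest at 0.27, and 0.45 without the 3 windows of highest share). Fewer DNA copies or poor mappability may lower the background there, and neither was tested.

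The highest folds, but not folds in general, lay near chromosome ends more often: the median fold was 20.43 within 5 Mb of an end and 20.83 elsewhere. Of the 100 peaks of highest fold, 28 were within 5 Mb of an end of a chromosome's span (the long-arm end alone for chromosomes 13, 14, 15, 21 and 22), against 14.5 ± 3.44 (mean ± SD) in 10000 permutations of fold within chromosomes (one-sided permutation p = 0.0006), which argues against chance placement, although the observation itself prompted the test; keeping the highest peak of each cluster left the count at 28, against 12.7 ± 3.28, and is no separate evidence. The share with an FDR of 0 was 15.7% near ends (95% Wilson interval 14.6 to 16.9%) and 16.9% elsewhere (16.4 to 17.4%), while the share on the 3.317 step was 6.25% (5.53 to 7.07%) and 3.95% (3.70 to 4.21%). Among the 14245 peaks in windows at or below the median step share, of which 11.04% lay near an end against 14.4% of all placed peaks, 13 of their own 100 highest folds lay near an end against 9.09 ± 2.73 (one-sided permutation p = 0.1081), which met the outcome set beforehand for low local background, a permutation share of 0.05 or more. That reading was withdrawn after the result was seen, because 13 still exceeds the permutation mean by more than 1 SD and a share above the threshold does not show equal placement, so low local background and stronger binding near ends cannot be told apart.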
